A study of Mus musculus with 9 samples.

How the data were processed

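RNA was profiled in 3 mouse cell lines on Affymetrix Mouse Gene 1.0 ST arrays, with 1 biotin-labelled array per sample. Trizol was used to extract total RNA, per the labels' protocols. The lines were a trophoblast stem cell line (129R3), an induced pluripotent stem cell line made with Oct4 and another made with OSKM, each with 3 arrays that the labels call biological repeats of that line. Each group therefore holds repeats of a single line, and a p-value measures the spread between these repeats, not between independently derived lines. The labels give the same mouse strain for all 9 samples. An embryonic stem cell line that the series design names as a control comes from another series and was not analysed here. Groups and replicate numbers were taken from the sample titles.

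The deposited values were array intensities on a linear scale, all above 0, for 35556 probe sets on each of the 9 arrays. GCOS 1.4 is named in the submitters' processing notes. The methods of background correction, probe summarization and normalization are not given in the sources used here. The array medians lay between 49.2 and 51.6 intensity units. On the log2 scale the standard deviation over arrays was 0.0245 for the lower quartile, 0.0245 for the median and 0.0495 for the upper quartile. The plan, made before the data were examined, was to use the values as deposited if this spread was at most 0.1 log2. Spread was read as a standard deviation; the range of the upper quartiles, 0.146, exceeds that limit. Quantile normalization was therefore computed as an alternative.

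Values were transformed as log2(intensity + 1). A log2 difference on this scale understates the change of a gene near the lowest intensities. A platform annotation table paired 21789 probe sets with 1 gene symbol, 1621 with several and 12146 with none. Probe sets with several symbols or none were left out of the gene tests. Gene identifiers were looked up in a RefSeq gene table of mouse assembly GRCm38.p6, where 21698 probe sets matched and 0 symbols changed. That table was used for names, chromosomes and gene order, and no coordinates are given because no genome build is stated for the array. The result was 19938 genes, of which 999 had several probe sets. For these the probe set with the highest mean over the 9 arrays was used. Among the named genes, the dimmer probe sets of Dab2 and Eed showed log2 differences of -0.04 and 0.09 between Oct4-iPS and trophoblast stem cells, against 0.76 and 1.02 for the probe sets used. No gene was filtered out for a low signal.

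Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with all 9 arrays in 1 fit and no covariate. The 3 comparisons were Oct4-iPS minus trophoblast stem cells, OSKM-iPS minus trophoblast stem cells, and Oct4-iPS minus OSKM-iPS. A gene was called when its Benjamini-Hochberg adjusted p over all 19938 genes was below 0.05, and calls of at least 2-fold were counted separately. All p-values are two-sided. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.084. There were 25 gene lists fixed before the data were examined. Each with at least 3 measured genes was tested with camera at a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation.

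Genes were named by a rule fixed before the data were examined. It takes the 4 reprogramming factors, a panel of 11 pluripotency, trophoblast, imprinted and X inactivation genes whatever their values, and the 7 highest and 7 lowest called differences of at least 2-fold whose arrays do not overlap between groups. Symbols of predicted or uncharacterized genes (Gm or LOC with digits, or ending in Rik) were left out of these 14. The rule adds up to 4 called members of each list with the largest differences. Members that were not called may also be named, with their values. H19, a panel gene, had no usable probe set.

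The script was tested on simulated data with known answers, drawn for 19938 genes, with 50 changed at each size. With so few changed genes the adjusted threshold is stricter than in the real data, so the shares recovered do not carry over to it. In the simulated comparison of Oct4-iPS with OSKM-iPS it recovered 12% of genes changed by 0.25 log2, 86% of those changed by 0.5 and 100% of those changed by 1. It made 13 calls among unchanged genes. For Oct4-iPS against trophoblast stem cells the shares were 4%, 86% and 100%, with 10 such calls. In simulated data for Oct4-iPS against trophoblast stem cells with 1 raised list, camera called 0 of the 23 other lists. The simulated genes were drawn independently, so this check cannot show list calls that arise from correlation between genes. For the genes shared by both lines against the same trophoblast arrays, 100 sets of unchanged groups were simulated.

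Alternatives covered the variance model, array weights, a replicate block, the groups in the fit, the normalization, a filter on dim genes, the choice of probe set, the threshold, the pseudocount and each array left out in turn. A run without X-linked genes was chosen after seeing the data. Whether the replicate numbers pair arrays across groups was also checked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.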

Results

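Gene expression was measured in 3 mouse cell lines, with 3 arrays each. Trophoblast stem cells (TSC) are the self-renewing precursors of the placental trophoblast. Oct4-iPS is an induced pluripotent stem cell line made with the transcription factor Oct4, which the gene Pou5f1 encodes. OSKM-iPS is a line made with Oct4, Sox2, Klf4 and c-Myc. Values are log2 array intensities, given as mean ± SD over 3 arrays, and differences carry the standard error of the limma fit. Across genes, which are not independent replicates, arrays of the same line correlated at r = 0.9955 to 0.9974. Arrays of the 2 iPS lines correlated with each other at 0.9917 to 0.9932, and with TSC at 0.9393 to 0.9425. The first principal component held 86% of the variance and separated TSC from both iPS lines, and the second, with 6.23%, separated the iPS lines from each other.

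The first comparison asks how the line made with Oct4 differs from trophoblast stem cells. Pou5f1 rose at least 184-fold, from 4.16 ± 0.17 in TSC to 11.68 ± 0.02 in Oct4-iPS (SD, n = 3). The fold is a lower bound because the TSC value lies below the lower quartile of all probe sets on the TSC arrays (4.24 to 4.25). The differences from TSC of Tdgf1, Lefty2, Zfp979, Mmp3, Mael, Tex11 and Dcn are lower bounds for the same reason, in both iPS lines. Nanog, a core pluripotency regulator, rose 100-fold, from 5.29 ± 0.02 to 11.93 ± 0.03. Klf4 rose 17.7-fold, from 5.63 ± 0.31 to 9.78 ± 0.09. Sox2 was already at 10.99 ± 0.06 in TSC and rose by 0.25 log2 (SE 0.07), to 11.24 ± 0.08. Myc fell 2.33-fold, from 9.42 ± 0.06 to 8.21 ± 0.13. The Oct4 probe set does not separate transcripts of the endogenous gene from any of an introduced one as far as the sources used here tell.

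Of 19 measured pluripotency transcription factors, 18 rose (18 adjusted over the list alone), with a median log2 difference of 1.65 (camera adjusted p = 7.17e-13). Prdm14, a naive-state regulator, rose by 3.84 (SE 0.08). Zfp42 rose by 1.47 (SE 0.06), while Esrrb, which TSC also express at 9.87 ± 0.13, rose by 0.57 (SE 0.07). Utf1 had a difference of -0.02 and was not called. Of 23 other pluripotency-associated genes, 22 rose (22 adjusted over the list alone; camera adjusted p = 8.06e-17). Tdgf1, a Nodal co-receptor, had the highest called difference of all eligible genes, at least 8.41 (SE 0.07) or 340-fold, from a TSC value of 3.89 that also lies below that quartile. Dppa5a rose by 6.23 (SE 0.08), Lefty2, a Nodal antagonist, by at least 5.46 (SE 0.09) and Tcl1 by 4.55 (SE 0.07). The amino acid transporter gene Slc7a3 rose by 6.42 (SE 0.07), the junctional adhesion gene Jam2 by 6.24 (SE 0.11) and the zinc finger gene Zfp979 by at least 5.54 (SE 0.20).

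Trophoblast stem cell genes fell together. Of 22 measured members, 21 fell (21 adjusted over the list alone), with a median of -3.29 (camera adjusted p = 1.67e-17). Elf5, a trophoblast transcription factor, fell 42.6-fold, from 9.99 ± 0.07 to 4.58 ± 0.08. Log2 differences were -4.41 (SE 0.08) for Gata3, -4.28 (SE 0.09) for Eomes and -3.13 (SE 0.12) for Cdx2, the trophectoderm regulator, and all of these fell. Tfap2c fell by 1.61 (SE 0.08) and kept a level of 8.78 ± 0.05. The X-linked homeobox gene Rhox9 fell by 4.73 (SE 0.10), while Krt7 fell by 5.04 (SE 0.07) and Bmp8b fell by 4.45 (SE 0.10). The lowest called differences included the actin-bundling gene Lcp1 at -6.06 (SE 0.09), Morc4 at -5.36 (SE 0.09) and the ubiquitin ligase gene Rnf128 at -5.22 (SE 0.11). Of 18 differentiated trophoblast genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), led by Hand1 at -3.05 (SE 0.08), and the list was not called (camera adjusted p = 0.0788).

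Epithelial genes fell in 11 of 16 cases (11 adjusted over the list alone), with a median of -1.35 (camera adjusted p = 1.92e-07). The simple-epithelium keratin genes Krt18, Krt8 and Krt19 fell, with differences of -5.86 (SE 0.08), -4.73 (SE 0.09) and -4.45 (SE 0.08). All 20 fibroblast genes rose (20 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 2.36e-11). With an estimated correlation the fibroblast list had adjusted p = 0.178. The smooth muscle actin gene Acta2 rose by 4.56 (SE 0.18), and the collagen gene Col1a2 by 4.37 (SE 0.13). Beside this fibroblast signal, 9 of 12 mesenchymal transition genes rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00033; adjusted p = 0.303 with an estimated correlation). They were led by the stromal protease gene Mmp3 at no less than 3.45 (SE 0.13) and vimentin, Vim, at 3.15 (SE 0.08).

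Germline genes rose in 10 of 16 cases and fell in 4 (10 and 4 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.0173; with an estimated correlation, adjusted p = 0.183). Mael, of the piRNA pathway, rose by at least 3.48 (SE 0.12), and the meiotic genes Tex11 and Hormad1 by at least 2.78 (SE 0.13) and by 2.27 (SE 0.23). Of 9 MHC class I presentation genes, 7 fell (7 fell and 1 rose adjusted over the list alone), with a median of -0.97 (camera adjusted p = 0.000472; with an estimated correlation, adjusted p = 0.0756). Erap1, which trims peptides, fell by 2.89 (SE 0.11), and the peptide transporter gene Tap1 fell by 2.59 (SE 0.10). Xist, the RNA that coats the inactive X chromosome, fell 18.4-fold, from 10.71 ± 0.03 in TSC. The maternally expressed Meg3 rose 7.11-fold, from 5.41 ± 0.23 to 8.24 ± 0.21. In all, limma called 9782 of 19938 genes, 4921 higher and 4861 lower in Oct4-iPS, and 2096 of them differed at least 2-fold (857 higher, 1239 lower). Of the 24 lists tested, 8 were called, and 4 held with an estimated correlation: both pluripotency lists, the trophoblast stem cell list and the epithelial list.

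**Figure D1:**
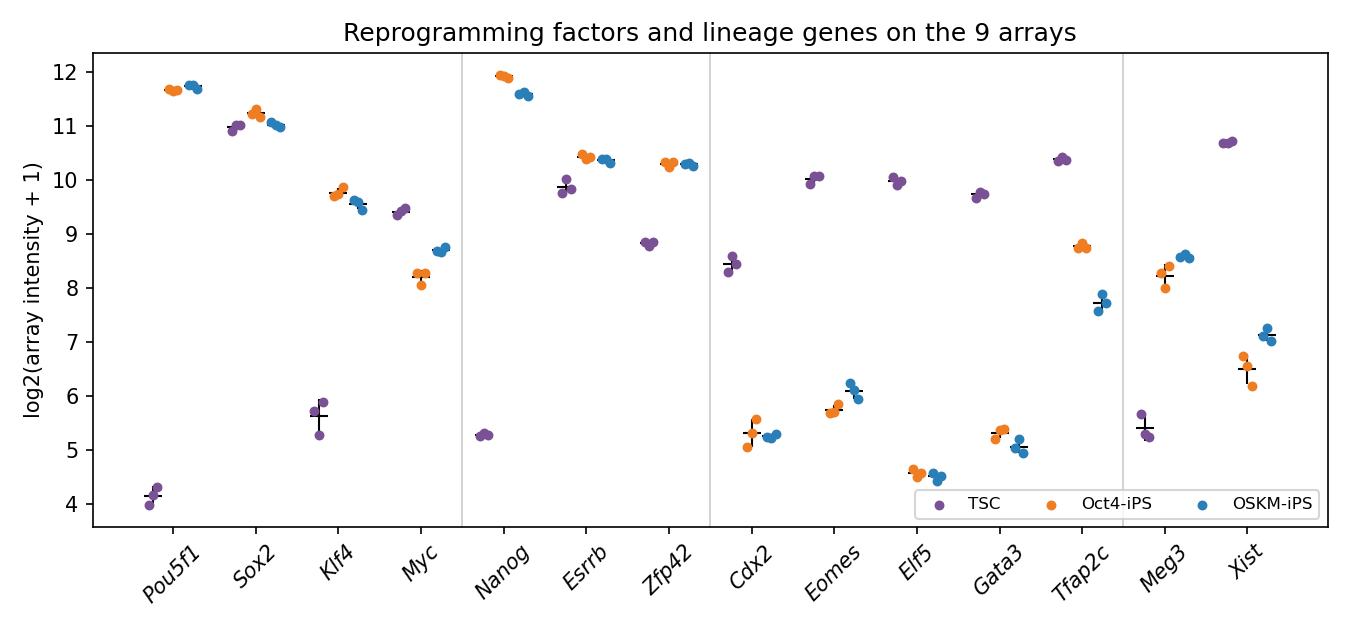
Log2(array intensity + 1) of the 4 reprogramming factors and 10 measured panel genes on each of the 9 arrays, with points for arrays, horizontal lines for means and vertical bars for SD (n = 3). Pou5f1 and Nanog lie above 11 in all iPS arrays and below 6 in TSC, whereas Sox2 lies near 11 in all 3 lines.

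The second comparison puts the line made with OSKM against the same trophoblast stem cells. Pou5f1 rose at least 192-fold, from the same TSC value below the lower quartile, to 11.74 ± 0.04 in OSKM-iPS (SD, n = 3), Nanog rose 80-fold, to 11.61 ± 0.04, and Klf4 rose 15.2-fold, to 9.56 ± 0.10. Sox2, at 11.03 ± 0.05, differed from TSC by 0.04 log2 (SE 0.07) and was not called (adjusted p = 0.713). Myc fell 1.64-fold, to 8.71 ± 0.05. Of 19 pluripotency transcription factors, 18 rose (18 adjusted over the list alone; camera adjusted p = 1.73e-14), and of 23 other pluripotency-associated genes 20 rose (21 adjusted over the list alone; camera adjusted p = 6.54e-17).

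Tdgf1 again had the highest called difference, a lower bound of 8.53 (SE 0.07), followed among these genes by Dppa5a at 6.09 (SE 0.08). Prdm14 rose by 3.15 (SE 0.08), Gdf3, a growth factor of pluripotent cells, by 4.65 (SE 0.10), Zfp42 by 1.46 (SE 0.06) and Esrrb by 0.50 (SE 0.07). The microtubule regulator gene Stmn2 rose by 5.84 (SE 0.16), Slc7a3 by 6.17 (SE 0.07) and Jam2 by 6.05 (SE 0.11). Of 22 trophoblast stem cell genes, 21 fell (21 adjusted over the list alone), with a median of -2.99 (camera adjusted p = 9.45e-18). Rhox9 had a difference of -5.51 (SE 0.10), Elf5 of -5.48 (SE 0.07), Krt7 of -4.87 (SE 0.07) and Gata3 of -4.67 (SE 0.08). Eomes fell by 3.92 (SE 0.09), Cdx2 fell by 3.20 (SE 0.12) and Tfap2c fell by 2.65 (SE 0.08). Lcp1 again had the lowest called difference, -6.15 (SE 0.09). Rnf128 fell by 5.62 (SE 0.11) and Morc4 fell by 5.48 (SE 0.09). Of 18 differentiated trophoblast genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0521).

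All 20 fibroblast genes rose in OSKM-iPS as well (20 adjusted over the list alone), with a median of 2.29 (camera adjusted p = 1.73e-14; with an estimated correlation, adjusted p = 0.111). Acta2 rose by 5.26 (SE 0.18), Col1a2 by 4.94 (SE 0.13) and the proteoglycan gene Dcn by at least 4.30 (SE 0.13). Beside them, 10 of 12 mesenchymal transition genes rose (10 adjusted over the list alone; camera adjusted p = 1.76e-06; with an estimated correlation, adjusted p = 0.165), led by Mmp3 at no less than 4.31 (SE 0.13). Of 16 epithelial genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 2.27e-05; with an estimated correlation, adjusted p = 0.0529). Krt18 stood lower at -5.68 (SE 0.08), Krt8 at -4.58 (SE 0.09) and Krt19 at -4.41 (SE 0.08). Of 9 MHC class I presentation genes 7 fell (7 adjusted over the list alone; camera adjusted p = 0.000571; with an estimated correlation, adjusted p = 0.0796). Among 16 germline genes, 10 rose and 4 fell (10 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.164). Xist fell 11.9-fold, to 7.13 ± 0.11, and Meg3 rose 9.06-fold, to 8.59 ± 0.04. In all, limma called 9521 of 19938 genes, 4668 higher and 4853 lower, and 2111 differed at least 2-fold (936 higher, 1175 lower). Of the 24 lists tested, 7 were called, and 3 held with an estimated correlation: both pluripotency lists and the trophoblast stem cell list.

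Both lines shared many of these genes. Of the 7 highest and 7 lowest differences that were named, 6 and 7 were the same genes in both lines. In the same direction and at least 2-fold, limma called 1731 genes against TSC in both lines, 703 higher and 1028 lower. None was called at least 2-fold in opposite directions, also at an unadjusted p below 0.05 (0 genes), while 42 were called in opposite directions at any size. Independent lists of these lengths would share 40.2 and 73 genes. Unchanged groups simulated against the same TSC arrays shared 0 in each of 100 simulations. Groups without any change were bound to share almost none at these limits, so this 0 cannot tell how much of the overlap comes from the shared arrays. Across genes, the log2 differences correlated at r = 0.953, against 0.501 in the simulations. Their covariance was 0.489, against 0.0043 in the simulations from the shared arrays alone, a difference of 0.485. The 3 TSC arrays are too few to be split, so part of the excess in overlap may come from sharing them. Another 365 genes passed the 2-fold limit in Oct4-iPS alone and 380 in OSKM-iPS alone; a direct test between the lines called 221 and 219 of these.

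**Figure D2:**
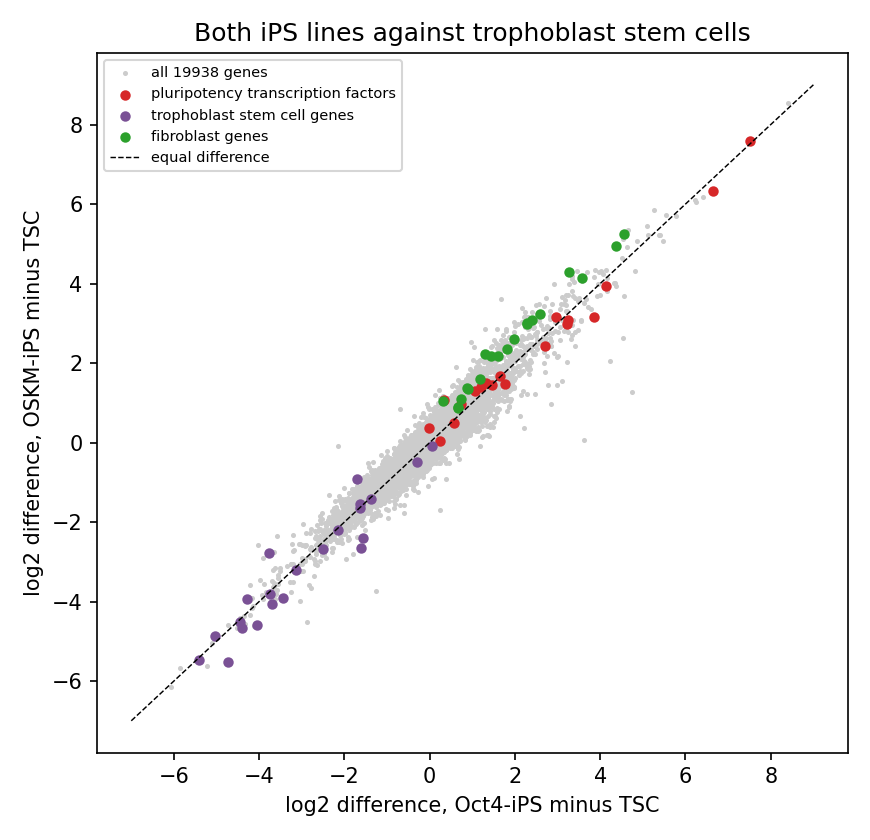
Log2 difference from TSC of each of the 19938 genes in Oct4-iPS (x axis) and OSKM-iPS (y axis), with 3 gene lists coloured and a dashed line of equal difference. Genes follow the line (r = 0.953), and all 20 fibroblast genes lie above it, with a median log2 difference between lines of -0.60.

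The third comparison asks how the line made with Oct4 alone differs from the line made with OSKM. Pluripotency regulators were close: the interval of the difference was -0.25 to 0.12 log2 for Pou5f1, -0.10 to 0.23 for Esrrb and -0.12 to 0.14 for Zfp42 (95%, from the limma fit). Nanog was higher in Oct4-iPS by 0.32 (SE 0.06; adjusted p = 0.00391), and Myc was lower, with a difference of -0.50 (SE 0.08; adjusted p = 0.00143). Klf4 and Sox2 each differed by 0.21 and were not called (adjusted p = 0.327 and 0.0585). Of 19 pluripotency transcription factors, 3 were higher and 4 lower in Oct4-iPS (6 and 6 adjusted over the list alone), and of 23 other pluripotency-associated genes 9 were higher and 5 lower (11 and 5 adjusted over the list alone). Neither list was called (camera adjusted p = 0.901 and 0.194), while Tcl1 was higher by 0.86 (SE 0.07) and Prdm14 by 0.69 (SE 0.08), and Gbx2 was lower at -0.72 (SE 0.09) and Utf1 at -0.40 (SE 0.07). In all, 2877 genes were called, 1285 higher and 1592 lower in Oct4-iPS, and 56 differed at least 2-fold (31 higher, 25 lower). Of the higher and lower calls, 143 and 34 lay on chromosome 10 (938 genes tested) and 263 and 44 on chromosome 11 (1563). Another 62 and 20 lay on chromosome 18 (470) and 183 and 25 on the X chromosome (739). Genes of these chromosomes also shifted as sets between the lines, as described below, so these calls cannot all be read as differences of single genes.

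The highest differences belonged to Pnma5 at 3.55 (SE 0.11), Usp26, a testis-expressed deubiquitinase gene, at 3.48 (SE 0.09), Klhl13, a ubiquitin ligase adaptor gene, at 2.46 (SE 0.07) and Fmr1nb at 2.19 (SE 0.08). All 4 genes lie on the X chromosome. Of the 31 genes at least 2-fold higher in Oct4-iPS, 11 were X-linked, against 3.71% of all tested genes (Fisher's exact test, p = 7.24e-09), a property examined after seeing the data. Pnma5 stood at 8.35 ± 0.09 in Oct4-iPS, 4.79 ± 0.21 in OSKM-iPS and 4.74 ± 0.17 in TSC. Next came the adenylate kinase gene Ak4 at 1.95 (SE 0.08), Calcoco2, an autophagy receptor gene, at 1.91 (SE 0.08) and the meiotic gene Hormad2 at 1.87 (SE 0.08). The lowest differences were those of Phlda2, an imprinted growth regulator of the placenta, at -2.07 (SE 0.07), Septin1 at -1.93 (SE 0.07), Dusp27 at -1.57 (SE 0.07), Cyp2b23 at -1.54 (SE 0.09), Cspg4b at -1.53 (SE 0.14), the cell cycle inhibitor gene Cdkn1c at -1.45 (SE 0.10) and Nckap1l at -1.37 (SE 0.11).

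Imprinted genes moved both ways: of 28 measured, 10 were lower and 4 higher in Oct4-iPS (15 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0802). Phlda2 stood at 7.38 ± 0.11 in Oct4-iPS, and at 9.45 ± 0.03 in OSKM-iPS against 9.53 ± 0.05 in TSC. Cdkn1c stood at 6.80 ± 0.21, 8.25 ± 0.05 and 10.82 ± 0.05 in the same order. Sfmbt2 was higher in Oct4-iPS by 1.62 (SE 0.06) and Impact by 1.18 (SE 0.06). Meg3 differed by -0.35 (SE 0.12) and was not called (adjusted p = 0.0843). Of 22 trophoblast stem cell genes, 6 were higher and 3 lower in Oct4-iPS (8 and 3 adjusted over the list alone; list not called, camera adjusted p = 0.0763). Tfap2c was higher by 1.05 (SE 0.08) and Ets2 by 0.85 (SE 0.09), while Id2 was lower at -0.99 (SE 0.07) and Bmp4 at -0.80 (SE 0.07). Eomes differed by -0.36 (adjusted p = 0.0202), Gata3 by 0.26 (adjusted p = 0.0555), Cdx2 by 0.06 (adjusted p = 0.794) and Elf5 by 0.06 (adjusted p = 0.618). Xist was lower in Oct4-iPS at -0.63 (SE 0.12; adjusted p = 0.00472).

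Germline genes were higher in Oct4-iPS in 8 of 16 cases and lower in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 3.77e-07; adjusted p = 0.08 with an estimated correlation), among them Tex11 at 1.33 (SE 0.13) and Dazl at 0.85 (SE 0.11). Fibroblast genes were lower in 17 of 20 cases (20 adjusted over the list alone; camera adjusted p = 3.74e-14; adjusted p = 0.124 with an estimated correlation), with Dcn at -1.04 (SE 0.13) and Lum at -0.95 (SE 0.13). Beside them, mesenchymal transition genes were lower in 9 of 12 cases (11 adjusted over the list alone; camera adjusted p = 2.46e-07; adjusted p = 0.124 with an estimated correlation), led by Cdh11 at -0.90 (SE 0.17). FGF-ERK response genes were lower in 7 of 14 (9 adjusted over the list alone; camera adjusted p = 3.71e-07; adjusted p = 0.124 with an estimated correlation), with the feedback inhibitor genes Spry2 at -1.05 (SE 0.09) and Dusp6 at -0.51 (SE 0.08). Epithelial genes were lower in 6 of 16 cases and higher in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00395; adjusted p = 0.124 with an estimated correlation), led by Cldn6 at -1.01 (SE 0.07). Cell cycle regulators were lower in 6 of 14 and higher in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0036; adjusted p = 0.124 with an estimated correlation), led by Cdkn1c and by Cdk6 at -0.87. Glycolysis genes were higher in 6 of 16 and lower in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.529 with an estimated correlation), led by Ldhb at 1.16 (SE 0.08). The list of Xist and Y-linked genes was lower in 3 of 4 (3 adjusted over the list alone, camera adjusted p = 0.00114, and 0.117 with an estimated correlation). Its Y-linked members Uty and Eif2s3y stood at 3.95 ± 0.14 and 4.07 ± 0.08 in Oct4-iPS, below the lower quartile of all probe sets on those arrays (4.27 to 4.32). Against TSC both were called higher, by 0.54 and 0.71 log2 in Oct4-iPS and by 1.13 and 1.25 in OSKM-iPS. The other Y-linked member, Kdm5d, differed from TSC by 0.18 in Oct4-iPS, not called, and by 0.35 in OSKM-iPS, called.

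With an estimated correlation, none of the 8 lists called in this comparison passed. The number of called genes was 1846, 1912 and 1881 when OSKM-iPS replicate 1, 2 or 3 was left out, and the Eomes call was lost without OSKM-iPS replicate 1 or 2 (adjusted p = 0.0855 and 0.063) and without Oct4-iPS replicate 1 or 2 (adjusted p = 0.0588 and 0.0676).

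**Figure D3:**
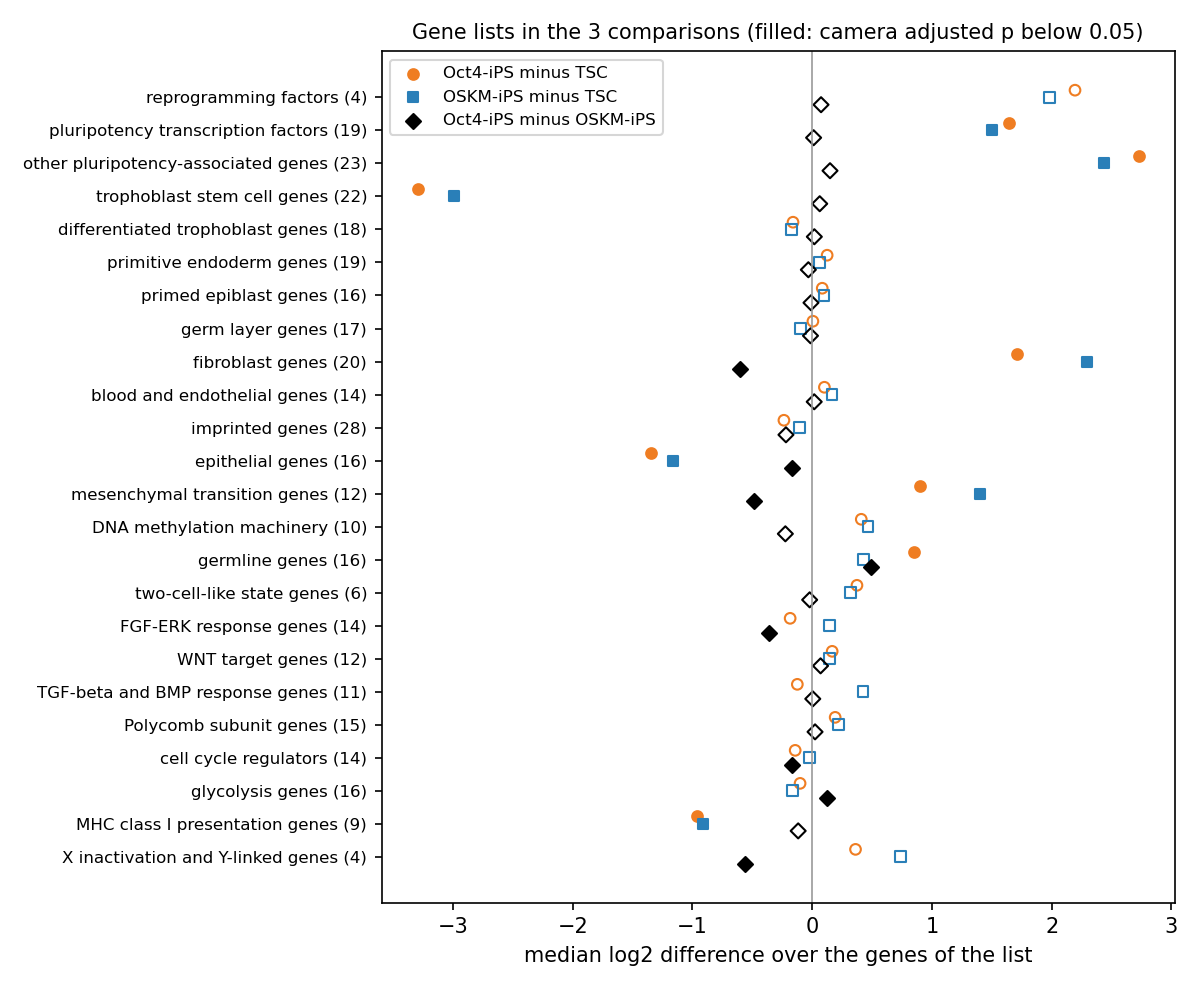
Median log2 difference over the measured genes of 24 lists (number of genes in brackets) in the 3 comparisons, with filled symbols for lists called by camera at the preset correlation and open symbols for the others. Pluripotency and fibroblast lists lie above 0 in both lines against TSC and trophoblast stem cell and epithelial lists below; between the lines the fibroblast list lies lowest, at -0.60.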

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

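Among the tests below, that of the epithelial genes and that of fibroblast RNA as a source of the X-linked difference were chosen only after the result was seen. A total of 42 genes were called higher than TSC in 1 iPS line and lower in the other, with a called difference between the lines. Of the genes named in the text 3 did so. Ak4 was 0.25 log2 higher in Oct4-iPS and lower in OSKM-iPS, at -1.70, a difference of 1.95. Cspg4b went the other way, with -0.69 and 0.84, a difference of -1.53. Suz12, a Polycomb subunit gene, stood at 0.27 and -0.30, a difference of 0.57. Among probe sets left out of the gene tests, 76 with several symbols and 278 with none were at least 2-fold higher in Oct4-iPS than in TSC, and 57 and 375 lower, in a fit of all probe sets.

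The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share below 0.05. In each comparison 1 split, the real one, gave as many calls. The real counts were 9782, 9521 and 2877, and the highest of the other splits was 0 in each by limma, with 753, 376 and 1251 genes at an unadjusted p below 0.05. Each other split mixes arrays of both lines, so the difference between the lines enters its spread and lowers its calls. The gap between these counts therefore does not decide on chance.

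Fibroblast genes were higher in both iPS lines than in TSC, and higher in OSKM-iPS than in Oct4-iPS. A separate set of 24 abundant fibroblast genes, of which 23 were measured and 6 reached a mean of 7 log2 in TSC, had a median of -0.625 between the lines (SD 0.235 over genes), with 23 of 23 below 0, which is what fibroblast RNA in unequal amounts would give, although 3 of the 23 were called lower in Oct4-iPS than in TSC (19 higher). A reciprocal epithelial shift of the cells between the lines predicted a mean of the epithelial genes above 0 by a set margin. Their mean was -0.191 (SE 0.085 over genes), so they were not higher in Oct4-iPS. This SE takes the genes as independent and does not measure the spread between arrays. With an estimated correlation, camera did not call the list lower (adjusted p = 0.124). The test does not decide on the shift, because its bounds were set after the result was seen. More fibroblast RNA in OSKM-iPS would also dilute epithelial genes there and predict a mean above 0. The test therefore cannot separate these explanations. Of the first list's 20 genes 2 stand in other lists and 2 reached that level in TSC, and its abundant member Col1a1 stood at 6.65 in TSC, 10.23 in Oct4-iPS and 10.79 in OSKM-iPS. The labels mention no feeder cells or sort, so RNA from feeder fibroblasts and fibroblast-like cells that arose in the cultures both stay open, as does a difference that comes with the factors used.

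X-linked genes were higher in both iPS lines than in TSC and higher in Oct4-iPS than in OSKM-iPS: the median over 243 X-linked genes with a mean of at least 7 log2 was 0.58, 0.33 and 0.26 in the 3 comparisons, against autosome medians of at most 0.04, 0.08 and 0.15. For Oct4-iPS against TSC a few strongly changed genes are argued against, since the lower quartile was also higher than the autosomal one by 0.346; this was not tested in the other comparisons. Fibroblast RNA that dilutes the X-linked excess in OSKM-iPS would raise pluripotency genes in Oct4-iPS over OSKM-iPS. The rise would be 1.13 with fibroblasts at the X-linked level of TSC, but 0.303 with no X-linked RNA in them. The 32 pluripotency genes at least 2-fold higher in both lines than in TSC had a median of 0.15 (SD 0.296 over genes, highest 0.864). These values argue against dilution by fibroblasts at the X-linked level of TSC. Dilution by fibroblasts with far less X-linked RNA stays open, since their level was not measured. A gain of expression from a silenced X chromosome, a hypothesis that goes with the lower Xist, predicts a smaller rise of genes that escape silencing. In Oct4-iPS against TSC the median of Kdm5c, Kdm6a, Eif2s3x and Ddx3x was 0.62. It exceeded the median of the other X-linked genes, 0.576, by 0.044, although Ddx3x, at 0.499, lay below 0.576. By the bound written before the result was seen, an escape median equal to or above the X-linked one, the result argues against the hypothesis. So it does by the standard error of the 4 genes, 0.038, with which the test was first scored. The wider bootstrap SD of 0.076, which exceeds the difference of 0.044, was adopted after that result was seen. Only by this later spread, and with 4 genes, does the hypothesis stay open. OSKM-iPS against TSC was not part of the test. There Kdm5c, Kdm6a, Eif2s3x and Ddx3x stood at 0.548, 0.467, 0.495 and 0.474, above the median of all X-linked genes, 0.334.

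Genes of chromosomes 10, 11 and 18 were slightly lower in OSKM-iPS. The median difference from the TSC mean was taken per array, relative to the other 16 autosomes. It was -0.19 to -0.18, -0.20 to -0.18 and -0.15 to -0.11 in OSKM-iPS, against 0.011 to 0.027, 0.021 to 0.035 and 0.017 to 0.09 in Oct4-iPS. Further tests used another measure, OSKM-iPS minus the average of the TSC and Oct4-iPS means, again relative to the other autosomes. A trend with expression level or gene length is argued against. On this measure the median of these 1162 genes was -0.199 before and -0.199 after a loess correction that moved genes by 0.053 (SD). On the same measure, a few regions are also argued against. There, 12 of 12 segments (4 per chromosome, split by gene order) lay more than 0.05 below the other autosomes (from -0.23 to -0.09), as did 12 of 64 segments of the others. A lower number of copies of these chromosomes in part of the OSKM-iPS cells may be proposed as a hypothesis; no DNA was measured.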

How the results depend on the processing

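No named gene or list that was called reversed its direction under any alternative run. The balance of calls did: the 4921 higher and 4861 lower calls of Oct4-iPS against TSC became 4204 and 5270 with median centring, with fewer higher than lower ones in most other runs too. The 31 higher and 25 lower 2-fold genes between the lines became 31 and 36 without Oct4-iPS replicate 1. With a stricter threshold, adjusted p below 0.01, the comparison of Oct4-iPS with OSKM-iPS had 1346 called genes. With limma's treat, which tests against a log2 difference of 1, the counts were 1363 for Oct4-iPS against TSC, 1366 for OSKM-iPS against TSC, 13 between the iPS lines and 1126 shared by both lines. With a pseudocount of 16 the genes at least 2-fold different between the iPS lines numbered 34. Against TSC, such genes numbered 1710 in Oct4-iPS and 1705 in OSKM-iPS. A larger pseudocount shrinks log2 differences by construction, most at low intensities. Leaving out arrays 1 at a time gave 1846 to 2776 called genes between the iPS lines, the lower values without OSKM-iPS replicate 1 (1846), 2 (1912) or 3 (1881), with fewer arrays in the fit. Lower calls between the lines fell from 1592 to 1003 without Oct4-iPS replicate 2 and to 952, 1037 and 1060 without OSKM-iPS replicate 1, 2 or 3, and higher calls from 1285 to 821 without OSKM-iPS replicate 3. Median centring moved the share of higher calls from 50.3% to 44.4% for Oct4-iPS against TSC and from 49% to 43.5% for OSKM-iPS. Of the values of named genes over all alternatives, 173 lost their call and 14 gained one, and of those of lists 16 lost it, each with the estimated correlation, and 12 gained it. Without X-linked genes, a run chosen after seeing the data, 9353, 9137 and 2629 genes were called, and the 31 genes at least 2-fold higher in Oct4-iPS than in OSKM-iPS became 20, against 24 lower. Same-numbered arrays of different lines did not deviate together: 0 of 9 pairs correlated over 0.1 (-0.087 to 0.028) and 0 of 9 arrays correlated best with their own number, so the numbers were not taken as pairs. With the replicate block, 9405, 9243 and 2394 genes were called. Genes with low intensities, such as the Y-linked ones in Oct4-iPS, are limited by background. In the simulated data, where few genes changed, most changes of 0.25 log2 were missed. The real data, with many more calls, have a less strict threshold, and Sox2 was called at 0.25 in Oct4-iPS against TSC.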

Other observations

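Single FGF-ERK response, cell cycle and DNA methylation genes changed in both iPS lines, in both directions, and none of these lists was called against TSC. The cyclin gene Ccnd2 rose by 3.70 log2 (SE 0.15) in Oct4-iPS and 4.28 (SE 0.15) in OSKM-iPS against TSC. Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, fell in both, with differences of -4.02 (SE 0.10) and -2.57 (SE 0.10). Of 14 cell cycle regulators 6 rose and 7 fell in Oct4-iPS, and 7 rose and 6 fell in OSKM-iPS (the same counts adjusted over the list alone; camera adjusted p = 0.855 and 0.636). In OSKM-iPS their median was -0.02, while the mean, 0.26, and the camera direction were above 0. Among 14 FGF-ERK response genes, 5 rose and 7 fell in Oct4-iPS and 7 rose and 5 fell in OSKM-iPS (the same counts adjusted over the list alone; camera adjusted p = 0.525 and 0.48). Etv1 rose by 3.34 (SE 0.11) and 4.19 (SE 0.11), while Dusp4 fell, at -2.25 (SE 0.12) and -1.66 (SE 0.12). Among 10 genes of the DNA methylation machinery, Tet1 rose by 2.81 (SE 0.07) and 2.54 (SE 0.07) and Tet2 by 2.73 (SE 0.07) and 2.43 (SE 0.07), with 6 higher and 2 lower in Oct4-iPS and 7 and 2 in OSKM-iPS (6 and 2, and 7 and 3, adjusted over the list alone; camera adjusted p = 0.173 and 0.0521).

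Markers of other states were mixed. Of 16 primed epiblast genes, 5 rose and 6 fell in Oct4-iPS and 6 rose and 5 fell in OSKM-iPS (the same counts adjusted over the list alone; camera adjusted p = 0.855 and 0.589), with Otx2 at 3.41 (SE 0.07) and 2.43 (SE 0.07). Of 17 germ layer genes, 3 rose and 5 fell in each line (the same counts adjusted over the list alone; camera adjusted p = 0.365 and 0.434), led by the receptor gene Kdr, which fell, at -4.13 (SE 0.06) and -4.62 (SE 0.06). In Oct4-iPS the germ layer median was 0.01, while the mean, -0.39, and the camera direction were below 0. Of 19 primitive endoderm genes, 5 rose and 5 fell in Oct4-iPS and 4 rose and 5 fell in OSKM-iPS (6 and 5, and 4 and 5, adjusted over the list alone; camera adjusted p = 0.972 and 0.975). In Oct4-iPS their median, 0.13, and the camera direction were above 0 and the mean, -0.11, below. Of 14 blood and endothelial genes, 4 rose and 4 fell in Oct4-iPS and 4 rose and 2 fell in OSKM-iPS (the same counts adjusted over the list alone; camera adjusted p = 0.855 and 0.589).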
